A study of Mus musculus with 12 samples.

How the data were processed

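RNA-seq of isolated glomeruli was analysed in 12 libraries, 3 mice in each of 4 groups (control and podocyte-specific Dach1 knockout, at baseline and after STZ). Per the labels' protocols, glomeruli were collected after perfusion with magnetic beads and total RNA was isolated from them. The values are read counts per gene symbol that the authors deposited as 1 table per library. Between 10.5% and 11.5% of the values of a library ended in 0.5, so the values were treated as estimated counts, as deposited and not scaled to depth, and rounded to whole numbers before any count model. The submitters' processing notes name BWA and mm10 without a role or version. The counting tool, annotation, strand handling and rule that gave the values ending in 0.5 are not given in the sources used here. No table held a 0, and 18 blank values (8 at baseline and 10 after STZ) were taken as 0. Every gene listed in the STZ tables reached a count of 100 in at least 1 STZ library, whereas 362 genes listed at baseline did not reach 100 in any baseline library, so the tables had been filtered differently before deposit. Gene symbols are those of the tables, and 15826 of 16298 symbols (97.1%) matched RefSeq genes of GRCm38.p6, the assembly that mm10 is built on, from which positions were taken.

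Replicates of a group were checked for duplicated libraries. The chi-square per degree of freedom between pairs ran from 42.0 to 352, so no pair agreed within sampling noise and all 12 libraries were used. Totals were 2.26e+07 to 2.49e+07 counts at baseline and 6.61e+07 to 7.86e+07 after STZ.

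Genes were filtered with edgeR's filterByExpr, scaled with TMM factors and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. Knockout and control were compared within each arm, on the 6 libraries of that arm. STZ and baseline were compared within each genotype, and the interaction was fitted on all 12 libraries, on the 13475 genes listed in both arms. Fold changes are on the log2 scale, with a standard error derived from the F statistic. CPM are TMM-scaled within the comparison. Intervals for ratios of counts are exact binomial 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

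The genes named in each comparison were set by a rule written before the data were examined. They were Dach1, Nell2 and Paxip1, then up to 10 genes with the largest positive and 10 with the largest negative log2 fold change past the threshold, with a mean of at least 1 CPM and groups that did not overlap (5 each, with no overlap rule, for the interaction). Where fewer than 5 passed in a direction, the genes of smallest p filled up to 5 and are given as not passing where they did not. Symbols of predicted genes and clone names were skipped and counted (1 called gene at baseline, 11 after STZ in the knockout comparison and 2 in the STZ comparison of knockouts). In the knockout comparison after STZ 1 gene that met the rule is left out of the text. Up to 4 members of smallest p were described per list, with some left out of the text. In a comparison of 3 against 3 without any effect, 10% of genes have groups that do not overlap. In the 4 comparisons between groups 11.8%, 14.9%, 19.8% and 21.6% of genes did, for knockout at baseline, knockout after STZ, STZ in controls and STZ in knockouts.

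A total of 31 gene lists (cell types, podocyte genes, pathways) was fixed before the data were examined. The lists were tested with camera on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. The list of mitochondrially encoded genes had no member in the tables, which left 30. With an estimated correlation none of the lists passed in any of the 5 comparisons. Another 4 lists were chosen after the results were seen. Sex was read from Xist and Ddx3y.

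The steps were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed genes. For the knockout at baseline (13472 genes), 0% of the genes changed by 1.5-fold, 19.4% of those changed by 2-fold and 89.4% of those changed by 4-fold were recovered, with 5 false calls among 77. For the knockout after STZ (16291 genes) the shares were 0%, 11.9% and 84.8%, with 2 false calls among 66, and for the interaction (13474 genes) 2.99%, 8.96% and 71.2%, with 4 false calls among 59. For STZ in controls (13473 genes) they were 1.49%, 29.9% and 97.0%, with 3 false calls among 88, and for STZ in knockouts (13473 genes) 1.49%, 17.9% and 87.9%, with 9 false calls among 80. No recovered gene had the wrong sign. By these shares, changes of 2-fold and below were mostly beyond the reach of 3 mice per group. On simulated counts for the knockout after STZ (16291 genes), camera at the preset correlation called the 1 shifted list and 0 of 20 unshifted lists. The simulated genes were drawn independently of each other. These counts therefore could not show how the list test behaves when genes are correlated.

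Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, other filters and thresholds, each library left out, all 12 libraries in 1 fit, the proximal tubule mean, immune mean or sex as a covariate, the sex-linked genes left out, the number in the baseline titles as a block, and the estimated correlation. Chosen after seeing the data were thinned STZ counts, the genes listed in both arms alone, fits without the tubule-rich libraries, and fits without genes with blank values or with values ending in 0.5 in only 1 arm. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.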

Results

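Glomerular RNA was sequenced from control mice and from mice lacking Dach1 in podocytes, the epithelial cells that carry the filtration slits of the kidney. Dach1 encodes dachshund-1, a nuclear protein that regulates transcription. Mice of both genotypes were studied untreated, as the baseline arm, and after streptozotocin (STZ), a toxin of insulin-producing beta cells that makes mice diabetic. The baseline mice were 10 weeks old, and STZ was given at 50 µg per g per day on 5 days, with RNA isolated 10 days later. Each of the 4 groups held 3 different mice. The baseline libraries listed 13480 genes with totals of 2.26e+07 to 2.49e+07 counts, and the STZ libraries listed 16293 genes with totals of 6.61e+07 to 7.86e+07. The 2 arms had 13475 genes in common. The series title names the search for genes regulated by DACH1, at baseline and in experimental diabetes, as the question.

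Dach1 lies on chromosome 14 from 97786846 to 98169765 (GRCm38.p6, RefSeq). It was lower in all 6 knockout libraries than in any control library of the same arm. At baseline its mean was 54.5 ± 6.39 CPM (SD, n = 3) in knockouts and 152 ± 42.0 CPM (SD, n = 3) in controls. The log2 fold change was -1.48 (SE 0.23), with an adjusted p of 0.111 in edgeR's quasi-likelihood test, so Dach1 itself was not among the genes called at baseline. After STZ its mean was 62.6 ± 6.87 CPM in knockouts and 166 ± 18.1 CPM in controls (SD, n = 3), a log2 fold change of -1.41 (SE 0.14, adjusted p = 0.00942). The remaining Dach1 counts were those of whole glomeruli, which hold other cell types besides podocytes, and their source was not tested. Nell2, which encodes a secreted glycoprotein of the neural EGF-like family, and Paxip1, which encodes the PTIP subunit of histone methyltransferase complexes, were named before the data were examined. Nell2 (chromosome 15, 95219440 to 95528796) had a mean of 586 ± 50.6 CPM in knockouts and 251 ± 104 CPM in controls after STZ (SD, n = 3). Its log2 fold change was 1.22 (SE 0.28) and its adjusted p 0.154, so it did not pass, although all 3 knockout values lay above all 3 control values. At baseline the log2 fold change of Nell2 was 0.37 (SE 0.36, adjusted p = 0.842). Paxip1 had log2 fold changes of 0.11 at baseline (adjusted p = 0.916) and -0.21 after STZ (adjusted p = 0.754).

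**Figure D1:**
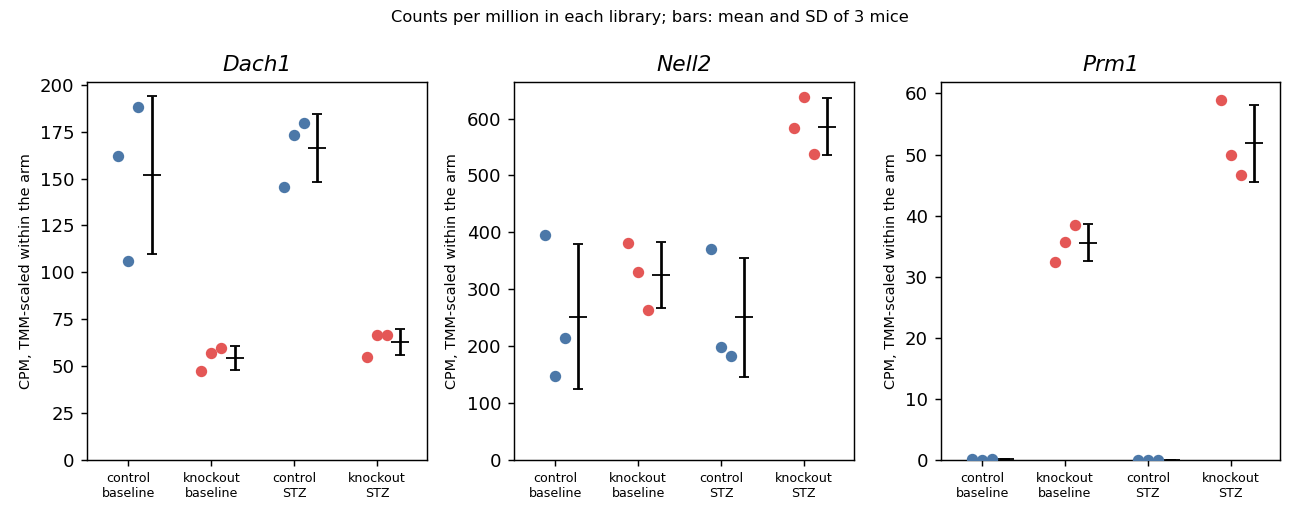
CPM of Dach1, Nell2 and Prm1 (y axes, scaled within each arm) in each of the 12 libraries, by group (x axis); points are mice, and the bars show the mean and SD of 3 mice. Dach1 was below 67 CPM in every knockout and above 105 CPM in every control, while Prm1 was at 32.4 CPM or more in every knockout and at 0.0867 CPM or less in every control.

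At baseline, 31 of 13475 genes differed between knockout and control glomeruli, 23 of them higher and 8 lower in knockouts. Among the higher genes were Adamtsl1, which encodes a secreted ADAMTS-like protein, at 51.7 ± 4.21 against 5.20 ± 0.483 CPM (SD, n = 3, log2 fold change 3.31, adjusted p = 0.000729), and Hpgds, a prostaglandin D synthase, at 17.6 ± 5.00 against 0.641 ± 0.0467 CPM (4.76, adjusted p = 0.00344). Aldh1a1, an enzyme that makes retinoic acid from retinaldehyde, stood 2.96 higher on the log2 scale (SE 0.20, adjusted p = 0.00900), and Ptgfr, the prostaglandin F receptor, 2.50 higher (SE 0.26, adjusted p = 0.0321). The other higher genes named by the rule were Fam26e (3.62), Il20ra, a cytokine receptor subunit (3.18), Gabrb1, a GABA-A receptor subunit (2.73), Txlnb (2.34) and Parm1 (2.25). Among the lower genes, Fgfbp1, a secreted binding protein for fibroblast growth factors, was at 2.21 ± 1.38 against 61.8 ± 17.8 CPM (SD, n = 3, log2 fold change -4.80, adjusted p = 0.0321), and the acid phosphatase gene Acpp at 16.7 ± 5.19 against 262 ± 64.2 CPM (-3.98, adjusted p = 0.0132). Lower too were Mgat5b (-2.74), Fam78b (-2.62), the mitochondrial topoisomerase gene Top1mt (-2.29), Metrnl (-1.56), the podocyte gene Rhpn1 (-1.53) and Mtss1, an actin regulator (-0.77).

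Prm1, a protamine gene normally read in spermatids, had 2440 counts over the 3 baseline knockouts and 4 over the 3 baseline controls, a depth-scaled ratio of 649 with a 95% exact interval of 253 to 2384 that covers counting error only. After STZ it had 11711 counts in knockouts and 5 in controls, a ratio of 2254 (966 to 6944). Prm1 (chromosome 16, 10796332 to 10796823) passed edgeR's quasi-likelihood test in both arms, with adjusted p-values of 0.00163 and 4.37e-05.

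Among the gene lists fixed before the data were examined, the list of other podocyte markers at baseline held 1 higher gene, Robo2, a guidance receptor (log2 fold change 1.63), and 1 lower gene, Rhpn1 (-1.53), of 26 measured. When adjusted over the list alone, 15 of the 26 passed, among them Npnt (0.76) and the cell cycle inhibitor gene Cdkn1c (-1.55). The median log2 fold change of the list was -0.34, and it passed the camera test downwards at a preset correlation (adjusted p = 0.000562) but not with an estimated correlation (adjusted p = 0.837 with an estimated correlation). None of the 14 measured podocyte transcription factors was called over all genes and 4 passed when adjusted over the list alone, among them Foxd1 (-0.67), Foxc1 (-0.40) and Lmx1b (-0.63). All 14 had a negative log2 fold change, and the list passed downwards at the preset correlation (adjusted p = 8.01e-05; adjusted p = 0.797 with an estimated correlation). None of the 21 slit diaphragm and cytoskeleton genes was called over all genes, and 1 passed when adjusted over the list alone, Nck2 (-0.55). Fn1, the fibronectin gene, was the 1 member called of 23 basement membrane and mesangial matrix genes (log2 fold change 2.00, adjusted p = 0.0321), and 2 passed when adjusted over the list alone, the other being Col4a6 (0.80). Eya4, a nuclear partner of DACH proteins, was the 1 called gene of 18 in the list of DACH, EYA and PTIP-complex genes (1.42, adjusted p = 0.0147), and it was also the 1 that passed when adjusted over the list alone.

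Markers of tubule cells differed more between baseline libraries than the genotypes did. The 24 proximal tubule genes had a mean log2 CPM of 6.19 in knockout replicate 1, 8.45 in replicate 2 and 9.17 in replicate 3, against 6.87, 7.83 and 7.08 in the controls. The difference between genotypes was 0.68 (exact two-sided permutation p = 0.6, where 0.1 is the smallest that 3 against 3 allows). In the camera test at the preset correlation the lists of the proximal tubule (median log2 fold change 1.01, adjusted p = 0.0112), the later tubule segments (0.71, adjusted p = 0.0127), oxidative phosphorylation (0.28, adjusted p = 0.000140), fatty acid oxidation (0.30, adjusted p = 0.0104), oxidative stress (0.31, adjusted p = 0.0311) and the cell cycle (0.35, adjusted p = 4.78e-06) passed upwards. Smooth muscle and renin cells (-0.41, adjusted p = 0.00589) and red blood cells (-0.73, adjusted p = 0.0127) passed downwards. None of these 8 lists had a member called over all genes. None passed with an estimated correlation (adjusted p = 0.891, 0.891, 0.891, 0.837, 0.837, 0.797, 0.797 and 0.837 in that order). Of these 8 lists, 6 lost the call without knockout replicate 3, namely the proximal tubule (adjusted p = 0.799), later tubule segments (0.319), oxidative phosphorylation (0.180), fatty acid oxidation (0.317), oxidative stress (0.128) and red blood cells (0.125). Calls were also lost without control replicate 3 (proximal tubule 0.0685, later tubule segments 0.0991, oxidative stress 0.195, fatty acid oxidation 0.211) and without knockout replicate 2 (proximal tubule 0.119, later tubule segments 0.108, red blood cells 0.108, oxidative stress 0.0620). The proximal tubule list lost it without control replicate 1 (0.0747) and red blood cells without control replicate 2 (0.128). In the smooth muscle and renin list, 3 of 8 genes passed when adjusted over the list alone, namely the renin gene Ren1 (-1.43), Akr1b7 (-1.61) and Rgs5 (-0.97). Across the 6 baseline libraries the first principal component, with 56.0% of the variance, followed the proximal tubule mean (absolute Pearson r = 0.993, exact permutation p = 0.00139, adjusted 0.00278; Spearman correlation of 1 in absolute value, exact p = 0.00278, adjusted 0.00556). Without the 2 libraries farthest from the median tubule mean the absolute r was 0.990. In the STZ arm, where this component held 42.6% of the variance, the absolute r with the proximal tubule mean was 0.948 (exact permutation p = 0.0125, adjusted 0.0125) but 0.627 without the 2 farthest libraries. The Spearman correlation there was 0.771 in absolute value (exact p = 0.103).

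The baseline count depended on single libraries. It was 5, 8 and 4 genes without control replicates 1, 2 and 3 and 51, 10 and 6 without knockout replicates 1, 2 and 3, with no called gene changing sign. DESeq2 called 220 genes (92 higher and 128 lower), and edgeR called 66 with the proximal tubule mean as a covariate, 7 with the immune cell mean and 10 with the sex of the mice.

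After STZ, 175 of 16291 genes differed between the genotypes, 137 of them higher and 38 lower in knockouts. Adamtsl1 (chromosome 4, 85513852 to 86428390) was at 125 ± 14.1 against 4.38 ± 0.411 CPM (SD, n = 3, log2 fold change 4.84, adjusted p = 6.66e-05), and Efemp1, an extracellular fibulin, at 634 ± 116 against 32.5 ± 10.7 CPM (4.29, adjusted p = 0.00293). Itga11, a collagen-binding integrin subunit, was 4.36 higher on the log2 scale (SE 0.18, adjusted p = 0.000294). Aldh1a1 reached 289 ± 86.9 against 13.7 ± 5.49 CPM (SD, n = 3, 4.39, adjusted p = 0.00654), and Parm1 110 ± 19.2 against 3.18 ± 1.23 CPM (5.11, adjusted p = 0.00169). Hpgds (4.62) and Ctxn3 (5.23) were also higher in knockouts. The potassium channel gene Kcnk15 had 1159 counts over the 3 knockouts and 6 over the 3 controls, a ratio of 186 with an exact 95% interval of 85.2 to 508 for counting error. The largest decreases that met the naming rule were in Opcml (-3.67), Acpp (-3.27), R3hdml (-2.78), Top1mt (-2.56), the anion transporter gene Slc26a7 (-2.54), Fam78b (-2.39), Nectin4 (-2.25), the bone morphogenetic protein receptor gene Bmpr1b (-2.11), the potassium channel gene Kcng2 (-1.96) and the connexin gene Gja3 (-1.96). Of the 175 genes, 20 were not listed in the baseline files (17 higher and 3 lower).

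Among STZ mice, podocyte genes differed between knockouts and controls in both directions. Of 26 other podocyte markers, Robo2 was higher in knockouts than in controls (log2 fold change 1.45, adjusted p = 0.0339). Lower in knockouts were Vegfa, the vascular endothelial growth factor gene (-0.89, adjusted p = 0.0241), Thsd7a (-1.34, adjusted p = 0.0298) and Cdkn1c (-0.77, adjusted p = 0.0465). When adjusted over the list alone 10 passed. Of 15 podocyte transcription factors Foxd1 was lower in knockouts (-0.72, adjusted p = 0.0428), and when adjusted over the list alone 3 passed, among them Lmx1b (-0.63). None of 21 slit diaphragm and cytoskeleton genes was called over all genes, and Dag1, the dystroglycan gene (0.92, adjusted p = 0.0603), passed when adjusted over the list alone.

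In knockouts against controls after STZ, the basement membrane and mesangial matrix list passed the camera test upwards (median log2 fold change 0.22, adjusted p = 0.000670). The call was lost with an estimated correlation (adjusted p = 0.984). With all 12 libraries scaled together, the list means were 7.63, 7.44 and 7.21 in STZ controls and 7.67, 7.98 and 7.79 in STZ knockouts. Baseline means were 7.58, 7.84 and 7.90 in controls and 7.76, 7.93 and 7.93 in knockouts. Knockout means were thus similar in both arms, while STZ control replicates 2 and 3 lay below every baseline library. At the preset correlation the list was also called for STZ against baseline in controls (camera, adjusted p = 0.00109). Of its 23 genes after STZ, Fn1 was at 178 ± 20.4 CPM in knockouts against 22.7 ± 6.53 CPM in controls (SD, n = 3, log2 fold change 2.97, adjusted p = 0.00388). The type IV collagen gene Col4a6 was 1.16 higher in knockouts on the log2 scale (adjusted p = 0.0122). In this comparison of genotypes 6 passed when adjusted over the list alone, including Col1a1 (0.76) and the laminin gene Lamb2 (0.54). Neither the 14 mesangial cell genes (median 0.04, adjusted p = 0.789) nor the 11 genes of the TGF-beta response list (median -0.21, mean 0.12, adjusted p = 0.981) passed as lists. Tagln, the transgelin gene, belongs to both the TGF-beta and the smooth muscle lists and was their 1 called member (log2 fold change 3.77, adjusted p = 0.0339). The circadian clock list passed downwards at the preset correlation (median -0.71, adjusted p = 0.00624; adjusted p = 0.984 with an estimated correlation), with no member of 15 called over all genes or when adjusted over the list alone. Its mean log2 CPM was 5.69, 5.59 and 4.78 in controls and 4.41, 4.98 and 4.96 in knockouts, so control replicate 3 lay within the knockout range, and the call was lost without control replicate 2 (adjusted p = 0.0991). Eya4 was higher in knockouts (1.88, adjusted p = 0.0122) and was the 1 called gene of 20 in the list of DACH, EYA and PTIP-complex genes. Nell2, which encodes a secreted glycoprotein and belongs to none of these groups, had also been placed in that list. In edgeR's quasi-likelihood test Nell2 passed when adjusted over the list alone (adjusted p = 0.0369) but not over all genes (adjusted p = 0.154). Because Nell2 was added to the list by choice, its pass there is no separate evidence of a change. The proximal tubule list did not pass (median -0.08, adjusted p = 0.789), its library means ranging from 6.55 to 8.45 in controls and 6.71 to 8.27 in knockouts. The STZ count was 84, 40 and 109 genes without control replicates 1, 2 and 3 and 62, 54 and 49 without knockout replicates 1, 2 and 3, with no called gene changing sign. DESeq2 called 565, and edgeR called 326 with the proximal tubule covariate and 63 with the sex of the mice. The only female STZ mouse was knockout replicate 2, so the sex covariate there marks that single library. It cannot tell sex from that mouse, without which 54 genes were called.

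The effects of the knockout were largely shared between the arms, which had no library in common. Of the 23 genes higher at baseline, 21 were also called higher after STZ (0.205 expected for independent lists, Fisher's exact p = 3.49e-42 over 13470 genes), among them Adamtsl1, Prm1, Hpgds, Aldh1a1, Parm1, Fn1, Ptgfr, Eya4 and Robo2. Of the 8 lower genes, 4 were also called lower (0.0208 expected, Fisher's exact p = 2.65e-09), namely Acpp, Top1mt, Fam78b and Metrnl. The other 4, Fgfbp1 (-4.86, adjusted p = 0.0568), Mgat5b (-2.26), Mtss1 (-0.91) and Rhpn1 (-1.27), had negative log2 fold changes after STZ without passing. In the other direction, 144 of the 155 genes called after STZ and measured at baseline had the same sign at baseline, against 58.8% of all genes, and 114 of the 144 had an unadjusted p under 0.05 there. Across 13470 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.437 and a Spearman correlation of 0.242. The r was 0.232 without STZ knockout replicate 1, 0.296 without STZ control replicate 1 and 0.569 without STZ control replicate 3.

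**Figure D2:**
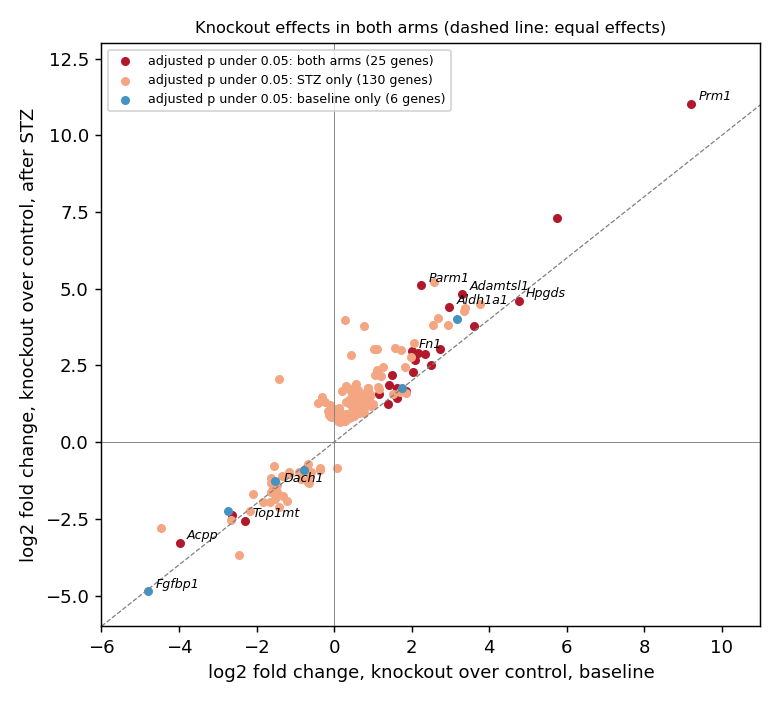
Log2 fold change of knockout over control at baseline (x axis) and after STZ (y axis) for the 161 genes measured in both arms and called in at least 1 of them; each point is a gene and the dashed line marks equal effects. 25 genes passed in both arms, 130 after STZ alone and 6 at baseline alone, and the genes called at baseline all kept their direction after STZ.

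The interaction of knockout and STZ asked whether the knockout effect differed between the arms. Adamtsl1 was the 1 gene of 13475 called by edgeR's quasi-likelihood test, with a knockout effect 1.52 larger on the log2 scale after STZ than at baseline (SE 0.17, adjusted p = 0.0440). The next genes by p did not pass: Parm1 (2.86, adjusted p = 0.0578), the periostin gene Postn (1.17, adjusted p = 0.0974), Camk2a (2.41, adjusted p = 0.163) and the elastic fibre gene Fbln5 (1.71, adjusted p = 0.163). No gene passed with a negative interaction, the smallest p there belonging to the ephrin gene Efna1 (-1.02, adjusted p = 0.559), followed by the growth factor gene Gdnf (-1.28), Piga (-1.09), Gtf2h2 (-0.85) and Sost (-1.27), with adjusted p-values of 0.852, 0.938, 0.946 and 0.975. The interaction of Dach1 was 0.07 (adjusted p = 0.989), that of Nell2 0.86 (adjusted p = 0.975) and that of Paxip1 -0.33 (adjusted p = 0.975). An unadjusted p under 0.05 was found for 494 genes, fewer than the 674 expected by chance. DESeq2 called 31 genes and limma-voom 0. Adamtsl1 passed in none of the 12 fits that left out 1 library, its adjusted p running from 0.0709 without baseline control replicate 2 to 0.177 without baseline control replicate 1. These fits called 2 other genes without baseline control replicate 2, 1 other gene without STZ control replicate 2 and 0 genes without any of the other 10 libraries. The adjusted p of Adamtsl1 was 5.50e-10 with DESeq2 and 0.113 with limma-voom.

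In controls, 31 of 13473 genes differed between STZ and baseline, 6 higher and 25 lower after STZ. Higher was Sost, which encodes the Wnt antagonist sclerostin, at 58.2 ± 6.70 against 13.4 ± 1.93 CPM (SD, n = 3, log2 fold change 2.12, adjusted p = 0.00598). Higher too were Aldh1a7 (2.02, a close relative of Aldh1a1 with which it could share reads), Ckap2 (1.65), Pmaip1, a pro-apoptotic target of p53 (1.57), Sec16b (1.35) and the complement regulator gene Cd55 (1.12). The lower genes included the growth factor gene Fgf1 at 31.5 ± 9.10 against 429 ± 12.1 CPM (SD, n = 3, -3.77, adjusted p = 0.00391). They also included the transthyretin gene Ttr (-5.13), Cstf3 (-3.77), the centrosome gene Cep97 (-3.57), Cacfd1 (-3.03), Pira6 (-2.75, of a family of near-identical receptors and so uncertain), Abca6 (-2.47), Itih4 (-2.41), Crebzf (-2.30) and Arpp21 (-2.27). Dach1 (0.11), Nell2 (-0.03) and Paxip1 (0.01) did not pass (edgeR's quasi-likelihood test, adjusted p = 0.866, 0.987 and 0.983). Of the 14 mesangial genes, Sfrp2, a secreted Wnt modulator, fell (-1.83, adjusted p = 0.0125), and 12 passed when adjusted over the list alone, including Pdgfrb (-1.24), Ptn (-1.07) and the desmin gene Des (-0.80). The list passed the camera test downwards at the preset correlation (median -0.93, adjusted p = 9.34e-13; adjusted p = 0.279 with an estimated correlation). The p53 response list passed upwards (median 0.41, adjusted p = 5.36e-07; adjusted p = 0.275 with an estimated correlation), with 6 of 15 genes passing when adjusted over the list alone, among them Ccng1 (0.61), Eda2r (1.59), Aen (0.71) and Gdf15 (2.10). The cell cycle list passed upwards (0.50, adjusted p = 1.19e-09; adjusted p = 0.403 with an estimated correlation), with 10 of 23 genes passing when adjusted over the list alone, such as Mki67 (1.24) and Ccnb2 (0.95). The glucose-responsive and insulin-signalling list passed downwards (-0.46, adjusted p = 0.00109; adjusted p = 0.275 with an estimated correlation), and 1 of its 14 genes, Foxo1 (-0.79), passed when adjusted over the list alone. In fry, which tests a list against no change, the mesangial, p53 and glucose lists each had an adjusted p of 0.0433. In the same test, which asks for a shift of a list in 1 direction, 2 lists passed for STZ in knockouts. There 0 passed for the knockout at baseline, the knockout after STZ and the interaction. The mixed form of fry, which counts changes in either direction, passed 4 lists for the knockout at baseline, 6 after STZ and 0 for the interaction. It passed 7 for STZ in controls and 12 for STZ in knockouts.

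In knockouts, 24 of 13473 genes differed between STZ and baseline, 15 higher and 9 lower after STZ. Cyp26a1, which encodes an enzyme that degrades retinoic acid, rose from 11.9 ± 3.71 to 93.4 ± 29.5 CPM (SD, n = 3, log2 fold change 2.97, adjusted p = 0.0416), and Parm1 from 21.7 ± 3.40 to 109 ± 18.9 CPM (2.33, adjusted p = 0.0137). Also higher were Kcnf1 (1.77), Serpinb6b (1.44), the semaphorin gene Sema3b (1.34), Slc38a4 (1.31), Ccbe1 (1.28), Adamtsl1 (1.26), the scavenger receptor gene Colec12 (1.24) and Tmem54 (1.20), Serpinb6b being of a family of close relatives and so uncertain. Lower were Cstf3 (-3.94), Cep97 (-3.52), Pira6 (-3.25), Cacfd1 (-2.94), Abca6 (-2.57), Crebzf (-2.05), the transcription factor gene Mecom (-1.62) and Brip1os (-1.02), whose counts cannot be told from those of an antisense partner because the strand handling is not given in the sources used here. Dach1 (0.19), Nell2 (0.83) and Paxip1 (-0.30) did not pass in knockouts (edgeR's quasi-likelihood test, adjusted p = 0.557, 0.129 and 0.406). The other podocyte markers passed upwards as a list (median 0.47, adjusted p = 3.86e-09; adjusted p = 0.329 with an estimated correlation), with no member called over all genes and 11 of 26 passing when adjusted over the list alone, such as Clic3 (1.03) and Rab3b (1.25). The same list passed upwards in controls (median 0.28, adjusted p = 6.19e-05; adjusted p = 0.596 with an estimated correlation), with 6 of 26 passing when adjusted over the list alone. The glucose-responsive and cell cycle lists passed in knockouts as in controls, downwards (-0.40, adjusted p = 0.0186; adjusted p = 0.638 with an estimated correlation) and upwards (0.32, adjusted p = 0.0331; adjusted p = 0.860 with an estimated correlation), with no member passing when adjusted over the list alone. In knockouts the cell cycle call was lost without baseline replicate 2 (adjusted p = 0.0600) or 3 (0.443) or STZ replicate 2 (0.170) or 3 (0.472), and the glucose call without STZ replicate 3 (0.0613). The mesangial list passed downwards (-0.80, adjusted p = 3.86e-09; adjusted p = 0.440 with an estimated correlation) and the p53 list upwards (0.34, adjusted p = 0.00325; adjusted p = 0.329 with an estimated correlation), with 12 of 14 and 1 of 15 genes passing when adjusted over the list alone. Between the genotypes, 7 genes were called lower after STZ in both (Abca6, Brip1os, Cacfd1, Cep97, Crebzf, Cstf3 and Pira6; 0.0167 expected, Fisher's exact p = 1.08e-18) and 0 were called higher in both. All 31 genes called in controls had the same sign in knockouts. Of the 24 called in knockouts, 19 had the same sign in controls, against 65.6% of all genes.

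Both STZ comparisons set libraries of different arms against each other, so treatment, depth and gene listing cannot be told apart. The age of the STZ mice is not given in the sources used here, so a difference in age between the arms cannot be excluded. The arms also differed in the sex of the mice and in the abbreviation that the titles give to controls, which also bears on the interaction. Its meaning is not given in the sources used here. By Xist and Ddx3y, replicates 1 and 2 of each baseline group were female (Xist 45.9 to 117 CPM) and replicate 3 male, while all STZ mice were male except knockout replicate 2 (Xist 146 CPM). The count in controls was 4, 10 and 12 genes without baseline replicates 1, 2 and 3 and 12, 4 and 12 without STZ replicates 1, 2 and 3, and that in knockouts 8, 1 and 7 and 8, 2 and 1 in the same order. Of those in knockouts only 1, 0 and 0 and 2, 0 and 0 were higher after STZ, so the majority of higher genes was lost without any single library. All 12 libraries in 1 fit gave 180 higher and 71 lower. DESeq2 called 410 genes in controls (145 higher and 265 lower) and 805 in knockouts (433 higher and 372 lower).

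Markers of other cell types differed between the arms. With the 6 libraries of a genotype scaled together, the mean log2 CPM of the mesangial list was 7.35 ± 0.290 after STZ and 8.31 ± 0.142 at baseline in controls, and 7.39 ± 0.234 and 8.17 ± 0.138 in knockouts (SD, n = 3). The immune cell list, of 16 macrophage and leukocyte genes, was at 3.94 ± 1.24 after STZ and 2.43 ± 0.185 at baseline in controls, and at 3.79 ± 0.782 and 2.30 ± 0.259 in knockouts. Among single libraries STZ control replicate 1 had the highest immune mean (5.37 with all 12 scaled together). Each of these differences between the arms had an exact two-sided permutation p of 0.1, the smallest possible. The immune list passed the camera test upwards at the preset correlation in both genotypes (adjusted p = 3.02e-06 in controls and 1.38e-08 in knockouts; adjusted p = 0.596 and 0.638 with an estimated correlation). None of its members was called over all genes, and 10 in controls and 13 in knockouts passed when adjusted over the list alone, among them Lyz2 (2.67) and Cd74 (2.31) in controls and C1qa (2.97) and C1qb (3.36) in knockouts. Endothelial markers were lower as a list in both genotypes at the preset correlation (median -0.34 and -0.50, adjusted p = 1.83e-05 and 2.83e-07; adjusted p = 0.596 and 0.638 with an estimated correlation). The slit diaphragm list had a median of 0.13 in controls (adjusted p = 0.303) and 0.25 in knockouts (adjusted p = 0.000110; adjusted p = 0.638 with an estimated correlation), with no member called over all genes.

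**Figure D3:**
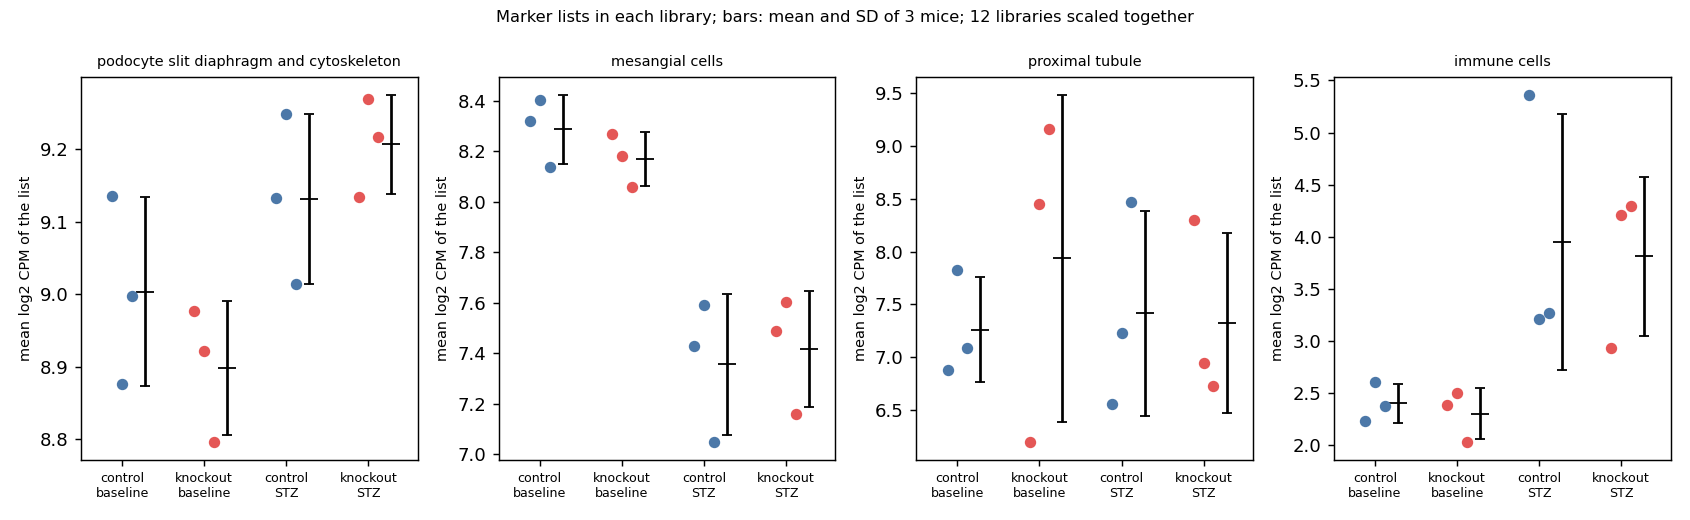
Mean log2 CPM of 4 marker lists (y axes) in each library by group (x axis), with all 12 libraries scaled together; points are mice, and the bars show the mean and SD of 3 mice. Mesangial means lay between 7.05 and 7.60 after STZ and between 8.06 and 8.40 at baseline, while proximal tubule means ranged from 6.19 to 9.17 across the baseline libraries.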

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

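The thinning of the STZ counts, the tests of Prm1, the tests of values ending in 0.5, the fit to the genes listed in both arms and the count of splits without the swapped genotypes were chosen only after the results they examine were seen.

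A difference between the arms brought up Adamtsl1, whose knockout effect was 1.52 larger after STZ on the log2 scale (edgeR's quasi-likelihood test, adjusted p = 0.0440). By the same interaction, tested with camera at a preset correlation, 4 lists of cell types differed between the arms, namely slit diaphragm genes (median log2 difference 0.16), smooth muscle and renin cells (0.87), proximal tubule (-1.10) and later tubule segments (-0.96). So did basement membrane and mesangial matrix (0.21), cell cycle (-0.19), oxidative stress (-0.42), fatty acid oxidation (-0.63), oxidative phosphorylation (-0.27) and circadian clock genes (-0.83). None of the 10 lists passed with an estimated correlation (the lowest adjusted p was 0.226), and 7 of them lost the preset call without at least 1 single library. When genotypes were regrouped within the arms, 6 of 100 drawn splits, the real one included, gave at least the 1 gene called in the real one. Among them, 1 split (419 genes) was the real genotypes swapped in 1 arm, which measures the knockout effect itself, and without it 5 of 99 did. Chance was thus not excluded for the interaction, and the highest of the others gave 1507. At baseline that split set control replicates 1 and 3 and knockout replicate 1 apart (proximal tubule means 6.19 to 7.08, others 7.83 to 9.17). After STZ it set control replicates 2 and 3 and knockout replicate 1 apart (7.22 to 8.47, others 6.55 to 6.94). It thus parted libraries of higher and lower proximal tubule mean in each arm, which points to a structure of the samples other than genotype. Adamtsl1 passed in none of the fits that left out 1 library.

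More genes were called for the knockout after STZ (175) than at baseline (31). Neither depth nor gene listing accounted for this, since 146 genes were still called on STZ counts thinned to the baseline depth over the genes listed in both arms (157 without thinning). With the proximal tubule mean as a covariate 66 were called at baseline and 326 after STZ, so the gap remained. A single covariate on 6 libraries cannot exclude that tubule RNA hid effects at baseline. The gap itself was not stable. With single libraries left out, the counts ran from 4 to 51 at baseline and from 40 to 109 after STZ. An effect of STZ itself was not tested apart from the sex and age of the mice and from the control mice. The ages in the STZ arm are not given in the sources used here. The control mice possibly differed between the arms since their titles carry different abbreviations. An effect of STZ thus stays open beside these differences. The count is no test of a larger effect, the interaction called 1 gene, and 144 of the 155 genes called after STZ had the same sign at baseline. Among the 10 splits of 6 libraries, which are too few for a share under 0.05, the highest other count was 1 after STZ and 559 at baseline, where that split put control replicate 2 with knockout replicates 2 and 3, the libraries of highest proximal tubule mean, and so points to a structure of the samples.

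Prm1 was counted at 32.4 to 58.9 CPM in every knockout library and at 0.0867 CPM at most in every control. Spermatid genes read more widely without DACH1 are argued against after STZ by the 18 other spermatid genes measured. Of these, 0 were called higher and their median log2 fold change was -0.036, although 2 had an unadjusted p under 0.05 (edgeR's quasi-likelihood test). At baseline 0 of 4 measured were called higher and 0 had an unadjusted p under 0.05. The list held 35 genes, so these 4 are too few to weigh. Changes of 2-fold and below were mostly out of reach. RNA from testis is argued against by the female knockouts, the lowest of which had 374 times the CPM of the highest control. What stays open is sequence of a Cre transgene counted as Prm1, since some such constructs end in protamine sequence. Prm1 in the 3 female knockouts averaged 0.820 of the 3 males, a ratio that mixes sex with arm (0.885 at baseline and 0.947 after STZ), so it was about as high in both sexes, as that explanation may predict, but the transgene used is not given in the sources used here.

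A few genes such as Cep97 had far lower counts after STZ in both genotypes (log2 fold change -3.57 in controls and -3.52 in knockouts). Gene models or isoform handling that differed between the arms may be behind it. The 197 genes with values ending in 0.5 in the STZ arm alone had a median log2 fold change of -0.16 in controls and -0.19 in knockouts, below all 10000 random gene sets of that size, and 5 and 4 of them were called lower and 0 and 1 higher, while the 84 genes with such values at baseline alone also had negative medians (-0.03 and -0.07), not the opposite shift. The shift of the 197 genes is small beside the change of Cep97, and of the 7 genes lower in both genotypes only Cep97 and Brip1os had such values, so an effect of STZ stays open for the other 5, although 15 instead of 25 genes were called lower in controls and 5 instead of 9 in knockouts when genes with such values in only 1 arm were left out. In the STZ comparisons, with 10 splits each and so no share under 0.05 possible, the real counts were 31 in controls and 24 in knockouts and the highest others 0 and 623, the last from a split that set baseline knockout replicates 2 and 3 and STZ knockout replicate 1, the tubule-rich ones, apart and again points to a structure of the samples.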

How the results depend on the processing

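The fits without the tubule-rich libraries were chosen only after the results were seen, as was the rule that a correlation had moved when it shifted by more than 1 SD of its leave-one-out values. The counts of genes called for the knockout at baseline (31), the knockout after STZ (175), the interaction (1), STZ in controls (31) and STZ in knockouts (24) were not stable, and the cause was not tested. DESeq2 called 220, 565, 31, 410 and 805 genes in that order, and an adjusted p under 0.1 gave 61, 302, 4, 56 and 111. All 12 libraries in 1 fit gave 79 and 293 for the knockout and 69 and 251 for STZ. With the proximal tubule covariate the knockout counts were 66 and 326, and with sex as a covariate 10 and 63. After STZ the sex covariate marks a single library, knockout replicate 2, and so is no adjustment for sex in general. Without the tubule-rich libraries 58 were called after STZ, on 2 mice against 2, and 5 at baseline, where 1 knockout against 3 controls was left and the count is not comparable. At baseline the immune cell covariate gave 7 and the title number as a block 60. For the interaction limma-voom called 0, and RLE and upper-quartile factors 2 each. With single libraries left out, the lowest and highest counts were 4 and 51 for the knockout at baseline, 40 and 109 after STZ, 0 and 2 for the interaction, 4 and 12 for STZ in controls and 1 and 8 in knockouts. The correlation of knockout effects between the arms (0.437) ran from 0.232 to 0.569. The lists called at the preset correlation numbered 10, 2, 10, 14 and 12 for the 5 comparisons and 0 in all 5 with an estimated correlation. Single libraries left out gave 4 to 17 lists at baseline, 1 to 11 after STZ and 6 to 15 for the interaction. The proximal tubule covariate gave 6 lists at baseline, and after STZ the sex covariate gave 5 and the fit without the tubule-rich libraries 10. In the baseline fit without the tubule-rich libraries, whose 1 knockout had the lowest proximal tubule mean, 5 lists changed direction, which for the tubule lists follows from how the libraries were chosen and tests nothing, with adjusted p-values of 3.42e-06 for the proximal tubule, 0.0300 for later tubule segments, 0.0781 for red blood cells, 0.736 for fatty acid oxidation and 0.000787 for oxidative phosphorylation. Among genes that did not pass in the main fit, Dach1 for the knockout at baseline passed in 2 of 22 alternatives (log2 fold change -1.68 to -1.30). Nell2 for the knockout after STZ passed in 3 of 23 (1.04 to 1.61). Small gene effects changed sign. Paxip1 at baseline (log2 fold change 0.11) was -0.0025 with the proximal tubule covariate, -0.13 without the tubule-rich libraries and -0.0052 to 0.28 with single libraries left out. The interaction of Dach1 (0.07) ran from -0.12 to 0.27. For STZ in controls Nell2 (-0.03) was 0.015 with limma-voom, 0.0030 with all 12 libraries and -0.42 to 0.46 with single libraries left out, where Dach1 ran from -0.093 to 0.29 and Paxip1 from -0.094 to 0.19. Over all alternatives, 1613 gene results were the same, 341 weaker, 16 stronger and 15 reversed, and 674 list results were the same, 130 weaker and 5 reversed. A gene result counted as the same when its sign and its side of the threshold were kept. Genes that passed in neither fit were thus included, and the interaction, with 1 gene called, gave 260 of the 1613.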

Other observations

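The tests of the matrix, retinoid and prostaglandin lists and of the genes near Dach1 were chosen only after the results were seen, while the calls of single genes come from the planned comparisons. Beyond the lists fixed in advance, 45 secreted matrix proteins were counted after STZ, a list written partly from genes already called and so not independent evidence. Of these, 14 were higher in knockouts and 0 lower, including the fibulin gene Efemp1, Svep1 (log2 fold change 2.46), the small leucine-rich proteoglycan genes Ogn (3.82) and Omd (1.76), Tnxb (1.69), Aebp1 (1.46), Frem1 (2.68) and the collagen cross-linking enzyme gene Lox (1.31). The median of the list was 0.66 (quartiles 0.27 and 1.31), with an unadjusted camera p of 0.000694 with an estimated correlation. Of the 31 members that were not called, 26 had a positive log2 fold change (median 0.34), where 46.6% of all genes did. At baseline 3 of 39 members were higher (Adamtsl1, Fn1 and Frem1) and the median was -0.08. There 12 of the 36 not called were positive, where 52.4% of all genes were, so the uncalled members leaned the other way.

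Genes of retinoid and prostaglandin metabolism stood among the calls without their lists moving as a whole. Among STZ mice, Aldh1a1, which makes retinoic acid, and Cyp26a1 (log2 fold change 3.99), which degrades it, were higher in knockouts than in controls and Rarres1 lower (-1.16), of 17 measured in the retinoid list (median -0.02, with an unadjusted camera p of 0.349). In the prostaglandin list Hpgds and Ptgfr were higher in both arms and Ptgds (1.68) after STZ, of 18 measured (median 0.07, with an unadjusted camera p of 0.110). With Dach1 itself left out of the count, no gene within 20 Mb of its start was called, of 39 measured at baseline and 47 after STZ. Over all genes 31 of 13475 and 175 of 16291 were called, so few or none were likely there and the count decides nothing. C130060K24Rik, chosen after its values were seen, was higher in both arms, by 5.76 at baseline and 7.32 after STZ on the log2 scale (adjusted p = 0.000158 and 4.37e-05, edgeR's quasi-likelihood test).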
